A study of Mus musculus with 18 samples.

How the data were processed

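Total RNA of mouse colon was homogenized in TRI Reagent, purified on RNeasy columns and reverse transcribed with the FastKing kit, per the labels' protocols. The deposited table holds TPM for 35976 gene symbols in 18 libraries, as made by the authors, and the submitters' processing notes name the genome build mm10 and the software DRAGEN 4.0.3 without saying what each did. How reads were counted, the annotation and the strandedness are not given in the sources used here. Each column sums to 1000000. TPM divides counts by gene length and by the library total, so an abundant class of transcripts, such as those of the mitochondrial genome, lowers the value of all other genes, and the sequencing depth cannot be recovered. The precision of low values is therefore unknown beyond the spread between replicates.

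Groups and replicate numbers were taken from the sample titles, and the assignment of TNBS to the vehicle and ISM012-042 groups from the design text of the series. All 18 columns matched a sample by name. No 2 libraries were identical, and the highest correlation of log2 values between a pair was 0.986. The table held 27 symbols converted to dates by a spreadsheet and 4 entries with duplicated symbols, which were kept apart. Of the symbols, 32496 matched the RefSeq table of GRCm38.p6, the assembly of mm10, which gave the coordinates, 1-based, of the named genes.

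Values were transformed to log2(TPM + 1). Genes with a TPM of at least 1 in at least 6 libraries were tested, 14129 in all. The 3 comparisons were fitted in limma 3.58.1 under R 4.3.3, with all 18 libraries in 1 fit so that the groups share an estimate of the spread, empirical Bayes with trend and robust settings, no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. No count model was used because the values are not counts. Before the data were examined 41 gene lists were fixed for the tissue and treatment, with 699 genes, of which 586 were tested and 11 were absent from the table. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 41 lists, and again with an estimated correlation. After the data had been seen, an exact two-sided permutation of the mean list score per library was added, with 924 regroupings and adjustment over the lists.

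Genes named in the text follow a rule set beforehand. For vehicle against sham and for ISM012-042 against vehicle it takes the 6 passing genes of largest positive and of most negative fold change with a mean of at least 5 TPM in the higher group, leaving out predicted genes, immunoglobulin and T cell receptor segments and mitochondrial genes. Where fewer pass, those of smallest unadjusted p fill the 6. It adds up to 4 members of each list by unadjusted p, and a fixed set of genes of the hypoxia, barrier and cytokine response. Genes named outside the rule are said to be so.

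The shift of colitis genes under the compound was computed over all 20 splits of the vehicle libraries, and chance values for comparisons that share libraries came from 100 simulated draws. The analysis was tested on simulated data with 200 changed genes in 10 runs. The changed genes were drawn at random above a minimum mean level, and the noise was pooled over all groups. With whole residual libraries as noise, 67.3% of 2-fold, 94.8% of 4-fold and 97.3% of 8-fold changes were called for vehicle against sham, and 68.1%, 94.5% and 97.6% for ISM012-042 against vehicle. False calls in these runs had a median of 0 in both, and a mean of 508.3 for vehicle against sham and 0.8 for ISM012-042 against vehicle.

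Alternatives set beforehand were an estimated correlation in camera, pseudocounts of 0.1 and 5, no filter and a TPM minimum of 5, median-ratio scaling, quantile normalization, leaving out the 13 mitochondrial genes, fitting only the groups compared, array weights, plain empirical Bayes, the replicate number as a block, and leaving out each library in turn. Added after the data had been seen were the Hoxb13 level, the mitochondrial share or both as covariates, Hoxb13 with median-ratio scaling, fits within the libraries above and below a log2 Hoxb13 level of 5, and the permutation of list scores.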

Results

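RNA sequencing was carried out on 18 mouse colon samples collected on day 2, in 3 groups of 6. The sham group had no colitis. In the other groups colitis was induced with TNBS, a hapten that triggers acute inflammation of the colon, and the animals received either vehicle or ISM012-042. ISM012-042 is described in the series title as a gut-restricted inhibitor of PHD, the prolyl hydroxylases that mark hypoxia-inducible factor for degradation. The replicate numbers come from the sample titles, and nothing in the labels states that the samples came from separate animals, so the p-values measure the spread between these samples. Values are TPM, which sum to 1000000 in each library and keep no record of sequencing depth, so the depth is unknown and no counting interval can be given. Between 12681 and 14632 genes reached a TPM of 1 per library. Fold changes are differences of log2(TPM + 1), which understate the change of low genes, and are given with their SE.

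The comparison of vehicle with sham addresses what the colitis model did to the colon. The antimicrobial lectin Reg3b (chromosome 6, 78370885 to 78373466, GRCm38.p6) rose by 7.11 ± 1.56 on the log2 scale (n = 6 per group), from a mean of 23.2 ± 24.1 TPM in sham to 4886 ± 7168 TPM in vehicle (SD). S100a8 (chromosome 3, 90669071 to 90670034) and S100a9 (chromosome 3, 90692630 to 90695721), which encode the neutrophil protein calprotectin, rose by 6.63 ± 1.20 and 6.66 ± 1.19. The acute-phase genes Hp and Saa3 rose by 5.45 ± 1.19 and 4.94 ± 1.01, and Cxcl2, a chemokine that attracts neutrophils, rose by 4.88 ± 1.11. For these 6 genes the adjusted p from limma lay between 0.00605 and 0.0181.

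Of 15 measured neutrophil markers 4 rose, and 13 when adjusted over the list alone. Beside S100a8 and S100a9 these were Retnlg, at 4.15 ± 0.92, and Wfdc21, at 3.88 ± 1.04, which passed in 16 of 27 alternatives where the other 3 passed in 27. The mean score of the list, the average log2(TPM + 1) of its genes in a library, was 1.28 ± 0.21 in sham and 4.22 ± 2.13 in vehicle (SD, n = 6), with an exact two-sided permutation p of 0.00216, the smallest that 924 regroupings allow, and 0.0444 after adjustment over 41 lists. Of 21 antimicrobial and acute-phase genes 8 rose, and 10 rose and 1 fell when adjusted over the list alone. S100a8 and S100a9 belong to both lists. The antimicrobial score was 2.13 higher in vehicle, with the same exact p of 0.00216 and adjusted p of 0.0444. Each list passes this adjustment only because the other also stands at the smallest p. In the gene set test camera the adjusted p of both lists passed, at 3.65e-13 and 1.55e-08, and did not with an estimated correlation, at adjusted p = 0.556 for neutrophil markers and adjusted p = 0.230 for the antimicrobial list.

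Among 27 chemokines Cxcl2 and Cxcl3 rose, the latter by 3.91 ± 1.07 (passing in 26 and 15 of 27 alternatives), and 7 rose and 2 fell when adjusted over the list alone. The chemokine score differed by 1.01, with an exact permutation p of 0.0173 and an adjusted p of 0.118. None of 7 measured pro-inflammatory cytokines passed in limma over all genes, and 3 did when adjusted over the list alone. Il1b stood 3.56 ± 1.04 higher (adjusted p = 0.0611), Il1a 2.68 ± 0.84 higher, Osm 2.34 ± 0.73 higher (0.0805) and Ccl3, a chemokine, 3.48 ± 0.99 higher (0.0528). With median-ratio scaling these 4 genes passed, at adjusted p from 0.0202 to 0.0326. Tnf and Cxcl1 did not pass, at 0.87 ± 0.60 and 2.39 ± 0.94. Il6 was under the expression filter, with a mean of 5.09 ± 9.39 TPM in vehicle (SD, n = 6) and 0.109 ± 0.103 TPM in sham, as were Il12b and Ifng. Mmp7, which encodes a matrix-degrading protease, rose by 3.12 ± 0.74 and was the 1 gene of 25 in the extracellular matrix list to pass, also over the list alone. The cytokine, chemokine and matrix lists passed camera, each at adjusted p = 0.726 with an estimated correlation.

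Of 30 measured genes of the mature colonocyte 7 fell and 1 rose (9 and 1 when adjusted over the list alone), and 10 had positive fold changes. Aqp8 (chromosome 7, 123462294 to 123468003), a water channel of surface colonocytes, fell by 3.86 ± 0.73, from 833 ± 178 to 86.8 ± 87.0 TPM (SD, n = 6). Slc26a3 (chromosome 12, 31433142 to 31473922), the chloride-bicarbonate exchanger, fell by 2.66 ± 0.46, the phosphate transporter Slc20a1 by 2.80 ± 0.56 and the carbonic anhydrase Car4 by 1.51 ± 0.24. The gene that rose, Guca2b, at 1.39 ± 0.33, was chosen for naming after its value was seen. The score of the whole list differed by -0.46, with an exact permutation p of 0.117 and an adjusted p of 0.368, and its camera call at 0.0466 was lost at adjusted p = 0.797 with an estimated correlation.

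Of 21 junction genes 3 fell, Cldn23 by 0.69 ± 0.16, Ocln by 0.87 ± 0.24 and Marveld2 by 0.63 ± 0.17, with 6 lower and 1 higher when adjusted over the list alone. The camera call of this list at 0.0187 was lost at adjusted p = 0.797 with an estimated correlation. Cldn23 did not pass with median-ratio scaling, at adjusted p = 0.0737. Tjp1 at -0.71 ± 0.22 and Cldn2 at 1.18 ± 0.36 did not pass (adjusted p of 0.0756 and 0.0736) and passed with median-ratio scaling, while Cldn1 stood at 0.06 ± 0.22. Of 19 mucus and goblet cell genes 3 fell, Zg16 by 0.76 ± 0.21, Tff3 by 0.86 ± 0.24 and Fer1l6 by 1.26 ± 0.36, with 6 lower and 1 higher when adjusted over the list alone, and the median of the list was 0.11 while its score differed by -0.24. Over 27 alternatives Tff3 passed in 8, Zg16 and Fer1l6 in 12 each, Marveld2 in 14, Ocln and Ankzf1 in 15 each, Adh1 in 14, and Cldn23 in 23. Muc2, the main secreted mucin, stood at 0.39 ± 0.37. The membrane mucin Muc3 fell by 1.39 ± 0.27, and Hnf4a, a transcription factor of the epithelium, fell by 0.66 ± 0.15. Ppargc1a, a regulator of mitochondrial genes, fell by 1.61 ± 0.31, the detoxification genes Gstm3, Gstm1 and Adh1 fell by 0.94 ± 0.19, 0.87 ± 0.18 and 2.16 ± 0.60, and the colipase gene Clps, the only pancreas gene tested, fell by 1.42 ± 0.35. Of 33 measured genes in the fixed list of hypoxia-inducible factor targets Selenbp1 fell by 1.55 ± 0.26 and Ankzf1 fell by 0.69 ± 0.18, with 3 lower and 1 higher when adjusted over the list alone, and the score differed by 0.01 (exact permutation p of 0.970) with a median of -0.17. Cyp2d12, Cyp2d13, Trpv3, Mettl7a2 and Slfn4 were, with Aqp8, the 6 genes of the most negative passing fold change, these 5 from -3.42 ± 0.72 to -3.07 ± 0.77. Trpv3 passed in 20 and Slfn4 and Clps in 19 each of 27 alternatives, and Mettl7a2 in 15 of 26. Cyp2d12 and Cyp2d13, the latter annotated as a transcribed pseudogene, belong like Gstm1 and Gstm3 to families of similar copies. The upstream counting could have split the reads of such copies.

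Of 27 measured interferon-stimulated genes, which all had negative fold changes in vehicle, 12 fell and none rose in limma, and 22 fell when adjusted over the list alone. Rsad2 (chromosome 12, 26442743 to 26456452) fell by 2.66 ± 0.54, Oasl2 by 2.20 ± 0.51, Oasl1 by 1.64 ± 0.36 and Stat2, a transcription factor of the interferon response, by 1.43 ± 0.32. The score was 5.81 ± 1.24 in sham and 4.12 ± 0.47 in vehicle (SD, n = 6), with an exact permutation p of 0.0173 and an adjusted p of 0.118 over the lists. Its camera call at 3.65e-13 was lost at adjusted p = 0.556 with an estimated correlation. Sham ranged from 4.09 to 7.24, and sham replicates 3 and 4, at 4.70 and 4.09, lay inside the vehicle range of 3.67 to 4.99.

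**Figure D1:**
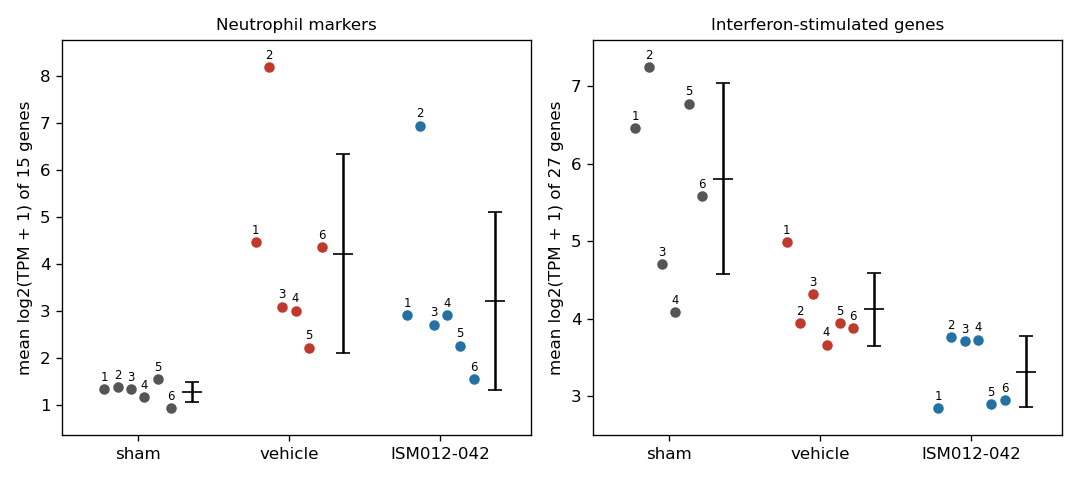
Mean log2(TPM + 1) per library of the neutrophil markers (left, 15 genes) and the interferon-stimulated genes (right, 27 genes), with replicate numbers at the points and mean ± SD (n = 6) beside them. The neutrophil score of every vehicle library lies above the sham maximum of 1.54, and the interferon score of every ISM012-042 library lies below the sham minimum of 4.09.

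In limma 46 genes rose and 584 fell of 14129 tested, 20 and 38 of them by over 4-fold, and 2554 had an unadjusted p under 0.05. The median of all genes was -0.07. With median-ratio scaling 511 rose and 1004 fell, so that 33.7% of the calls were higher instead of 7.30%, and with the mitochondrial genes left out 421 rose and 911 fell (31.6% higher). The count of 46 became 27, 22, 20 and 23 without sham replicates 1, 2, 4 and 5, 80 without vehicle replicate 1 and 27 without vehicle replicate 4, and the count of 584 became 314, 328 and 333 without sham replicates 2, 4 and 5, and 884, 345 and 319 without vehicle replicates 1, 4 and 5. By camera 12 lists were up and 4 down, none of them with an estimated correlation (smallest adjusted p = 0.230), and 2 passed the exact permutation of their scores, or 7 with median-ratio scaling.

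ISM012-042 was compared with vehicle to show the effect of the compound within colitis. No gene passed in limma, where the smallest adjusted p was 0.233, and 2688 genes had an unadjusted p under 0.05, 2670 of them higher and 18 lower. The interferon-stimulated genes stood lower under ISM012-042, with 25 of 27 negative. Isg15 (chromosome 4, 156199424 to 156200818), a ubiquitin-like interferon-induced protein, had a fold change of -1.78 ± 0.63 (n = 6 per group) and mean levels of 18.8 ± 10.8 TPM against 61.8 ± 20.1 TPM in vehicle and 495 ± 462 TPM in sham (SD). Ifit1, Oas3 and Oasl2 stood at -1.72 ± 0.61, -1.61 ± 0.63 and -1.43 ± 0.51, and Rtp4, an interferon-induced gene outside the list, at -1.15 ± 0.33. None of these passed (adjusted p from limma between 0.233 and 0.242), nor did any member when adjusted over the list alone, where 6 were lower with median-ratio scaling. These SE pool all 3 groups, and sham spread most, with an interferon score SD of 1.24 against 0.47 in vehicle and 0.46 in ISM012-042. The SE of the score difference was 0.47 with all 18 libraries and 0.27 in a fit on the groups compared. The genes named here did not pass in that fit either.

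The interferon score was 3.32 ± 0.46 under ISM012-042 and 4.12 ± 0.47 in vehicle (SD, n = 6), with an exact permutation p of 0.00866 and an adjusted p of 0.355 over the 41 lists. With median-ratio scaling the exact p was 0.00216, the smallest that 924 regroupings allow, and the adjusted p 0.0887. At this smallest p a list passes only if other lists also have small p, so the missed call does not count against a difference. All 15 neutrophil markers had negative fold changes with a median of -0.90, none passed over all genes or over the list alone, and the score difference of -1.01 had an exact permutation p of 0.416. S100a8 and S100a9 stood at -1.94 ± 1.20 and -1.90 ± 1.19. The antimicrobial score differed by -0.50, with an exact permutation p of 0.327, and the cytokine score by -0.76, with an exact permutation p of 0.383. Cxcl2, Cxcl3, Ccl3, Il1a and Il1b stood at -2.72 ± 1.11, -2.21 ± 1.07, -2.21 ± 0.99, -1.93 ± 0.84 and -1.73 ± 1.04. Vehicle replicate 2 and ISM012-042 replicate 2 had neutrophil scores of 8.19 and 6.95, while the other libraries of their groups reached 4.46 and 2.91.

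Genes under hypoxia-inducible factor were measured because PHD inhibition stabilises it. Of 33 feedback and adaptation targets none passed, over all genes or over the list alone, and the median fold change was 0.29, against 0.30 for all genes. Vegfa (chromosome 17, 46016993 to 46032377), Pdk1, Car9 and Egln3 stood at 0.51 ± 0.29, 0.52 ± 0.28, 0.40 ± 0.26 and 0.30 ± 0.53, and after median-ratio scaling at 0.19, 0.21, 0.08 and -0.01. The list members of smallest unadjusted p included Selenbp1 at 0.68 ± 0.26, Kdm4b at 0.47 ± 0.13 and Ankzf1 at 0.53 ± 0.18. The score was 4.83 ± 0.33 under ISM012-042, 4.61 ± 0.57 in vehicle and 4.60 ± 0.14 in sham (SD, n = 6), with an exact permutation p of 0.420 against vehicle. The camera adjusted p was 0.222, and adjusted p = 0.958 with an estimated correlation. Hif1a and Epas1, which encode the oxygen-regulated subunits, stood at 0.04 ± 0.58 and 0.47 ± 0.16, Egln1 and Egln2 at 0.29 ± 0.18 and 0.22 ± 0.12, and the barrier genes Nt5e, Adora2b, Cldn1, Ocln and Tff3 at 0.47 ± 0.94, 0.01 ± 0.33, 0.38 ± 0.22, 0.42 ± 0.24 and 0.20 ± 0.24. With median-ratio scaling Hif1a, Egln1, Egln2, Adora2b and Tff3 took a negative sign, at -0.28, -0.03, -0.10, -0.15 and -0.13. Epo was listed at 0 in all 18 libraries.

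The 6 genes of smallest unadjusted p in the higher direction, none of which passed, were Ttll10 at 0.89 ± 0.19, Phldb1 at 0.65 ± 0.15, Zmym6 at 0.63 ± 0.15, Caskin2 at 0.59 ± 0.14, Ap1g2 at 0.54 ± 0.13 and Clasrp at 0.52 ± 0.13. The median of all genes was 0.30, and after median-ratio scaling, which brought that median to 0.01, the 6 genes stood between 0.20 and 0.62. By camera no list was up and 12 were down, 6 of which had a median of the opposite sign. With an estimated correlation the antimicrobial list (adjusted p = 0.0178) and the interferon list (adjusted p = 0.0311) held as deposited, no list did with median-ratio scaling, and none passed the exact permutation of the deposited values, where the smallest adjusted p was 0.355. With median-ratio scaling 0 genes passed and 1052 had an unadjusted p under 0.05, of which 382 were higher and 670 lower, so that the direction of the majority turned. With the mitochondrial genes left out 0 passed and 1911 of 1989 were higher. Leaving out each library in turn gave 0 in each of the 12 fits. In simulated data of the same size limma called 68.1% of 2-fold and 94.5% of 4-fold changes in this comparison. The changed genes were drawn at random above a minimum mean level, and the noise was pooled over all groups. These rates therefore do not hold for genes of wide spread, such as Cxcl2 at -2.72 ± 1.11, which did not pass (adjusted p from limma of 0.246).

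**Figure D2:**
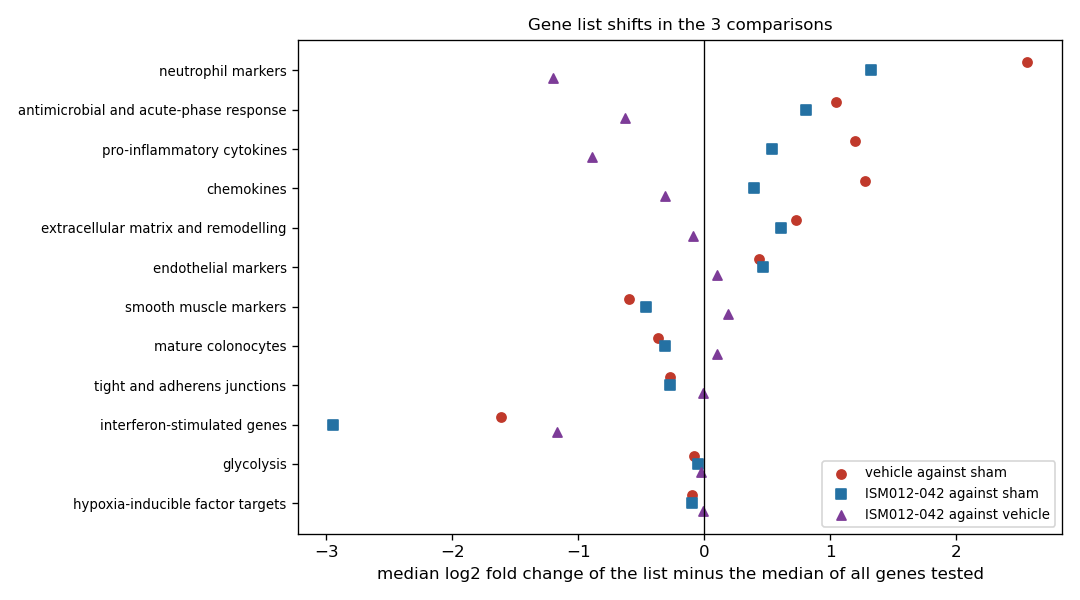
Median log2 fold change of each gene list minus the median of all 14129 genes tested (x axis), for vehicle against sham (circles), ISM012-042 against sham (squares) and ISM012-042 against vehicle (triangles), in 12 lists. The neutrophil list stands at 2.57, 1.33 and -1.20 and the interferon list at -1.61, -2.95 and -1.17, while the hypoxia-inducible factor targets stand at -0.10, -0.09 and -0.01.

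ISM012-042 was set against sham to show which differences from uninflamed colon were present under the compound. Interferon-stimulated genes differed most as a group, with 19 of 27 fallen and 23 when adjusted over the list alone. Isg15, Ifit1, Rsad2, Oasl2 and Rtp4 fell, at -4.07 ± 0.63, -4.01 ± 0.61, -3.74 ± 0.54, -3.63 ± 0.51 and -2.93 ± 0.33 (adjusted p from limma between 0.000666 and 0.00380). The score difference of -2.49 had an exact permutation p of 0.00216 and an adjusted p of 0.0222, and the camera adjusted p of 1.47e-51 became adjusted p = 0.0299 with an estimated correlation. With median-ratio scaling these were 0.0380 by the exact permutation and adjusted p = 0.362 with an estimated correlation. Hp rose by 5.97 ± 1.19, while Aqp8 fell by 3.10 ± 0.73 and Car4 by 1.38 ± 0.24, and over 27 alternatives Hp passed in 26, Aqp8 in 15 and Car4 in 27. Reg3b, S100a8 and S100a9 stood at 5.91 ± 1.56, 4.69 ± 1.20 and 4.76 ± 1.19 without passing (adjusted p of 0.0675, 0.0596 and 0.0554), and passed with median-ratio scaling.

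No neutrophil marker passed over all genes in limma and 4 did when adjusted over the list alone. The neutrophil score differed by 1.93, with an exact permutation p of 0.00433 and an adjusted p of 0.0355, while camera gave 0.0218, and adjusted p = 0.998 with an estimated correlation. Of 21 antimicrobial genes 1 rose, and 10 rose and 1 fell when adjusted over the list alone, and the score differed by 1.63 (exact permutation p of 0.00216, adjusted p of 0.0222) although camera gave 0.229. The 13 endothelial markers all had positive fold changes, with a score 0.71 higher (adjusted p of 0.0222 by the exact permutation, adjusted p = 0.998 in camera with an estimated correlation), and 7 rose when adjusted over the list alone. The monocyte and macrophage score was 0.89 higher (adjusted p of 0.0380 by the exact permutation, adjusted p = 0.998 in camera with an estimated correlation). The mesothelial score was 0.82 higher and the angiogenesis score 0.44 higher, with adjusted p of 0.0222 and 0.0380 by the exact permutation, and neither passed camera. The 11 adipocyte markers all had positive fold changes and a score 2.08 higher, at 3.26 ± 2.09 in sham, 4.13 ± 2.09 in vehicle and 5.35 ± 1.31 in ISM012-042 (SD, n = 6), with an exact permutation p of 0.0671 and an adjusted p of 0.197. None passed over all genes or over the list alone, the score ranged from 1.47 to 6.83 between libraries, and the camera call at 0.0275 was lost at adjusted p = 0.998 with an estimated correlation.

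In limma 77 genes rose and 123 fell against sham, and 2937 had an unadjusted p under 0.05. The median of all genes was 0.21. With median-ratio scaling 144 rose and 628 fell (18.7% higher instead of 38.5%), and with the mitochondrial genes left out 745 rose and 387 fell (65.8% higher). The count of 77 became 40, 22, 29, 51 and 24 without sham replicates 1 to 5 and 14, 38, 25 and 31 without ISM012-042 replicates 1, 2, 4 and 5, and the count of 123 became 69 and 70 without sham replicates 2 and 5 and 62, 75 and 72 without ISM012-042 replicates 1, 4 and 5. The neutrophil list lost its camera call without sham replicates 4 and 6, at adjusted p of 0.0514 and 0.0760, and without ISM012-042 replicate 2, at 0.104. By camera 5 lists were up and 7 down, 1 of them with a median of the opposite sign, and the interferon list alone held with an estimated correlation, and 7 lists passed the exact permutation.

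Both comparisons with sham shared 18 genes that rose and 103 that fell. Because both use the same sham libraries, 100 simulated pairs of unchanged groups were drawn, which shared a median of 0 in each direction and a mean of 52.7 rising and 1.48 falling genes, and independent lists would share 0.251 and 5.08. With the sham libraries split 3 and 3 the 2 comparisons shared a median of 1 rising and 10 falling genes over 20 splits. Across genes, which are not independent replicates, the fold changes correlated at 0.884, inside the simulated range of -0.119 to 0.902 around a mean of 0.522. Their covariance was 0.205, above the simulated range of -0.0051 to 0.114 around a mean of 0.0370. With split sham libraries the correlation was 0.718 and the covariance 0.182 (medians of 20 splits).

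Genes that responded to colitis were followed under ISM012-042 with the vehicle libraries split, 3 to call the genes against sham and 3 to compare with ISM012-042, relative to the median of all genes. Genes called higher, 1 to 2275 per split, had a median shift of -0.10 over 20 splits, from -2.65 to 0.26, and 12 of 20 splits were negative. Shifts from -2.65 to -0.52 arose only where vehicle replicate 1 helped call the genes and vehicle replicate 2 was compared with ISM012-042. Genes called lower, 4 to 3453 per split, had a median shift of -0.05, from -0.21 to 0.22, and 6 of 20 splits were positive. The sign of this median depended on the processing, at 0.03 with 15 of 20 positive without a filter, 0.03 with 12 of 20 with median-ratio scaling and 0.04 with 13 of 20 with quantile normalization. For genes called higher these medians were -0.05, -0.02 and 0.01. The covariance between the colitis fold change and the ISM012-042 fold change was -0.0435, inside the simulated range of -0.102 to 0.0148 for unchanged groups that share the vehicle libraries.

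Libraries differed within groups in the share of mitochondrial transcripts and in Hoxb13 (chromosome 11, 96194316 to 96196610), a homeobox gene of the distal colon that was chosen for naming after its values were seen. Mitochondrial transcripts took 33.8 ± 4.9% of the TPM in sham, 37.5 ± 13.5% in vehicle and 31.3 ± 6.9% in ISM012-042 (SD, n = 6), and the groups did not differ by exact permutation (p from 0.359 to 0.571). This share followed the first principal component, which held 34.9% of the variance, with an absolute Pearson r of 0.927 and Spearman rho of 0.928 over 18 libraries (permutation p of 1e-05, the smallest that 100000 resamples give, adjusted 3e-05 over 3 components) and r of 0.901 without the 2 libraries farthest from the median. Because TPM have a fixed sum, a larger mitochondrial share lowers the other genes together. Part of this correlation is therefore built in, and the permutation p does not separate that part. Hoxb13 ranged from 0.329 to 288 TPM, and its log2 value did not differ between groups by exact permutation (p from 0.171 to 0.626). Of the 11 libraries with higher Hoxb13, 4 were sham, 3 vehicle and 4 ISM012-042.

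Within these 11 libraries the neutrophil score was 4.32 higher in vehicle than in sham and the interferon score 1.43 lower, with exact permutation p of 0.0286 and 0.286. Within the 7 libraries of lower Hoxb13 the differences were 1.64 and -2.05, with an exact permutation p of 0.1 each, the smallest possible there. The interferon score under ISM012-042 differed from vehicle by -0.73 in the former (exact permutation p of 0.0286) and by -1.10 in the latter (exact permutation p of 0.1). The hypoxia-inducible factor score differed between vehicle and sham by 0.50 in the former and -0.54 in the latter, with exact permutation p of 0.0286 and 0.1, and with median-ratio scaling by 0.28 and -0.08. It differed between ISM012-042 and vehicle by -0.12 in the former and 0.47 in the latter, with exact permutation p of 0.514 and 0.2, and with median-ratio scaling by -0.21 and 0.04. In limma on the 7 libraries 3 genes were higher and 6 lower in ISM012-042, with 2 libraries, than in vehicle, with 3. These 3 vehicle libraries had the highest mitochondrial shares of all 18. In vehicle the Hoxb13 level and the mitochondrial share therefore divided the libraries in the same way. The comparisons with vehicle within libraries of higher or lower Hoxb13, those of the hypoxia-inducible factor score included, thus cannot separate the Hoxb13 level from the mitochondrial share. On the 11 libraries no gene passed, with 1327 at an unadjusted p under 0.05.

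**Figure D3:**
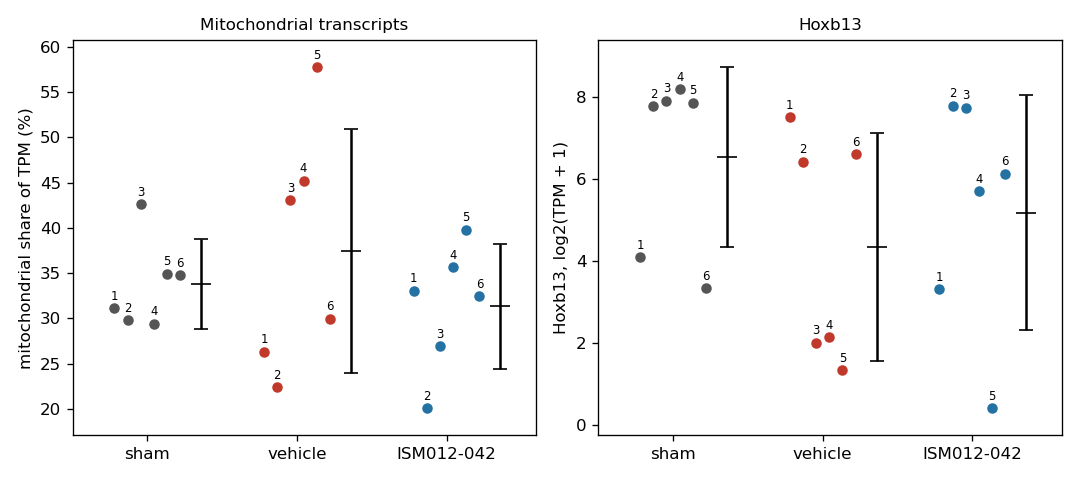
Share of TPM from mitochondrial transcripts in percent (left) and log2(TPM + 1) of Hoxb13 (right) per library, with replicate numbers at the points and mean ± SD (n = 6) beside them. Vehicle replicate 5 has the highest mitochondrial share, 57.8%, and ISM012-042 replicate 2 the lowest, 20.1%.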

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

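Every test of an explanation below was chosen after its result was seen, and only the counts over other splits of the libraries were planned before theirs. Among 285 tests of a named gene, a list score or the mitochondrial share within a group of 6, 28 had a library whose gap to the others exceeded Dixon's 95% limit. Chance gives about 1 in 20, or 14 here. ISM012-042 replicate 2 held 11, vehicle replicate 2 held 8, sham replicate 4 and vehicle replicate 1 held 3 each, vehicle replicate 5 held 2 and vehicle replicate 6 held 1.

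Vehicle replicate 2 and ISM012-042 replicate 2 stood far above their groups in genes of acute inflammation. In vehicle replicate 2 the calprotectin genes reached 10990 TPM (S100a9, others 70.89 to 359.1) and 12000 TPM (S100a8, others 73.78 to 434.8), Retnlg 1467 TPM (others 18.79 to 78.58), Cxcl1 182 TPM (others 2.66 to 10.12) and Il6 24.16 TPM (others 0.23 to 2.761). In ISM012-042 replicate 2 S100a9 reached 3019 TPM (others 14.18 to 86.16), Cxcl3 101.4 TPM (others 0.114 to 1.725), Osm 16.18 TPM (others 0.241 to 1.69) and Il6 27.22 TPM (others 0 to 0.244). Their neutrophil scores were 8.191 and 6.948, where the other libraries of the groups reached 4.457 and 2.908, and the cytokine score of ISM012-042 replicate 2 was 4.722 (others 1.982 to 2.845).

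ISM012-042 replicate 2 also had the highest hypoxia-inducible factor score of its group, 5.472 (others 4.537 to 4.81), with Vegfa at 90.89 TPM (others 37.12 to 47.85), Epas1 at 44.69 TPM (others 27.29 to 32.3) and Adora2b at 5.398 TPM (others 0.552 to 1.581). Vehicle replicate 2, which had no compound, reached a score of 5.52, the highest of all libraries. Selenbp1, a member of that list, was lowest in ISM012-042 replicate 2 and in vehicle replicate 2, at 247.8 TPM (others 596.4 to 803) and 207.5 TPM (others 378.4 to 459.9). Dbp was lowest in vehicle replicate 2, at 12.58 TPM (others 15.82 to 17.55). Vehicle replicate 1 was highest for Trpv3 at 18.24 TPM (others 0.071 to 1.811), Mettl7a2 at 10.64 TPM (others 0 to 0.269) and Ifng at 0.537 TPM (others 0 to 0.173). Vehicle replicate 5, with the highest mitochondrial share, was lowest for Zg16 at 3997 TPM (others 6451 to 8200) and Kdm4b at 3.89 TPM (others 5.402 to 6.391). Sham replicate 4 was highest for Slc26a3 at 1888 TPM (others 725.4 to 1025), Ttll10 at 10.7 TPM (others 5.467 to 6.695) and Phldb1 at 45.29 TPM (others 26.41 to 31.97), and vehicle replicate 6 for Ttll10 at 5.111 TPM (others 2.432 to 3.1).

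Interferon-stimulated genes were lower in ISM012-042 than in sham by a score of -2.49 ± 0.54 (SE, fit on the groups compared). The difference was -2.62 ± 0.55 with the mitochondrial share as a covariate and -2.43 ± 0.59 with the Hoxb13 level, and -2.55 ± 0.47 and -2.42 ± 0.49 in fits of all 18 libraries, which argues against either as the whole cause. The lowest of 15 cell type marker lists, smooth muscle, stood at -0.24 ± 0.27, so none of these lists fell by as much. Lists near the floor could not fall that far, as with the neutrophil score of 1.28 in sham. The mature colonocyte list was not among the 15, so a loss of cells is not excluded by this test. Against vehicle the difference was -0.92 ± 0.27 and -0.89 ± 0.23 with these covariates in the fit on the groups compared, a fit chosen after the 18-library fit had given -0.95 ± 0.49 and -0.85 ± 0.48, which decides nothing since it gave -0.80 ± 0.47 without a covariate, and neither covariate made the difference smaller, which argues against either as the whole cause. Colitis and the compound are the biological differences named by the design, and sham replicates 3 and 4 had low scores without either, so what sets the interferon level of a library remains open.

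Of 2688 genes with an unadjusted p under 0.05 between ISM012-042 and vehicle, 2670 were higher (382 of 1052 with median-ratio scaling), and the median of all genes was 0.30 (exact permutation p of 0.0801). With the mitochondrial genes left out 1911 of 1989 were higher and the median was 0.17 ± 0.06 (jackknife SE; exact permutation p of 0.00649), which argues against the mitochondrial share as the whole cause and leaves it open for part. Without vehicle replicate 5 the median was 0.19 ± 0.14, within 2 SE of 0, so that library stays open. The limit was first a bare 0.1, then 0.1 with the SE, then 2 SE from 0 with the permutation, each change made after the values were seen. The compound could also shift many genes, which was not tested apart from the other contents of the TPM.

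Other splits of the libraries were counted, 100 for each comparison with the real split included. For vehicle against sham 2 splits called at least the 630 genes of the real groups, the real one included, and the highest other called 1392. For ISM012-042 against sham only the real split called at least its 200 genes, and the highest other called 2. Both counts lie below 5 in 100 of the splits drawn. This does not exclude chance for either comparison. False calls for vehicle against sham in the simulated runs with whole residual libraries had a mean of 508.3 and a median of 0. False calls were not counted for ISM012-042 against sham alone. In the 100 simulated draws of unchanged groups the comparisons with sham shared a mean of 52.7 rising genes, with a median of 0. A few draws thus called many genes in both. For ISM012-042 against vehicle the real groups called 0 genes in limma, so every split reaches that and the count cannot test chance. In that comparison 2688 genes had an unadjusted p under 0.05, and the highest other split called 6097 genes. The splits of 1392 and 6097 genes part libraries of lower and higher mitochondrial share, with means of 29.1% against 42.2% and 26.4% against 42.4%. The split of 6097 genes also parts them by Hoxb13, with 6 of its higher libraries on the former side and 1 on the latter (4 and 3 in the split of 1392), so a structure of the libraries beside the groups is present and these measures are not separated there. Chance is not excluded for the lists called by camera, since 42 splits called at least the 16 lists of vehicle against sham (highest other 26), 92 at least the 12 of ISM012-042 against vehicle (highest other 28) and 76 at least the 12 of ISM012-042 against sham (highest other 25).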

How the results depend on the processing

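Chosen after the data had been seen were the settings with covariates, those within the libraries of higher or lower Hoxb13, Hoxb13 with median-ratio scaling, and the exact permutation of list scores. List values are the mean log2 fold change minus the median of all genes, except under the exact permutation, where they are the raw difference of scores. The hypoxia-inducible factor list kept its side of the threshold in all 3 comparisons under each alternative run, the shift of colitis genes moved by less than its spread with a sign that depended on scaling and filter, and no called value changed sign. The cause of the changes below was not tested, except that fewer libraries were fitted where stated.

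Between vehicle and sham 46 genes were higher as reported, 29 with a pseudocount of 5, 29 with no filter, 511 with median-ratio scaling, 541 with quantile normalization, 421 with the mitochondrial genes left out and 287 with array weights. The count was 167 with Hoxb13 as a covariate, 930 with the mitochondrial share, 787 with both, 792 with Hoxb13 and median-ratio scaling, 1028 in the 11 libraries of higher Hoxb13 and 110 in the other 7. The 584 lower genes became 1004 with median-ratio scaling, 928 with quantile normalization, 911 without mitochondrial genes, 308 with only the groups compared, 1267 with the mitochondrial share, 1083 with both covariates, 1083 with Hoxb13 and median-ratio scaling, and 279 and 1829 in the libraries of higher and lower Hoxb13. Leaving out 1 library gave 20 to 80 higher and 314 to 884 lower genes. With an estimated correlation the 12 lists up and 4 down became 0 and 0, which ended the calls of the interferon list at -1.62 (adjusted p = 0.556), the neutrophil list at 3.01 (0.556) and the antimicrobial list at 2.20 (0.230). The interferon list did not pass the exact permutation, at -1.69 (0.118).

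Between ISM012-042 and vehicle no gene passed in limma under the alternatives run (2688 at an unadjusted p under 0.05 as reported), except in the 7 libraries of lower Hoxb13. There 3 were higher and 6 lower, with 2 libraries of ISM012-042 and 3 of vehicle. Leaving out 1 library gave 0 to 0 genes in each direction. The 12 lists down became 5 with median-ratio scaling and 2 with an estimated correlation, which ended the call of the neutrophil list at -1.30 (adjusted p = 0.120). By the exact permutation the interferon list at -0.80 (0.355), the neutrophil list at -1.01 (0.664) and the antimicrobial list at -0.50 (0.664) did not pass.

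Between ISM012-042 and sham 77 genes were higher and 123 lower. With median-ratio scaling these were 144 and 628, with quantile normalization 257 and 546, without mitochondrial genes 745 and 387, with only the groups compared 477 and 232, with array weights 2322 and 938, and with the replicate number as a block 38 and 71. They were 1108 and 271 with Hoxb13 as a covariate, 1213 and 538 with the mitochondrial share, 468 and 300 with both, 228 and 787 with Hoxb13 and median-ratio scaling, 17 and 41 in the libraries of higher Hoxb13 and 45 and 195 in those of lower, and 50 were higher with no filter. Leaving out 1 library gave 14 to 104 higher and 62 to 125 lower genes. The 5 lists up and 7 down became 0 and 1 with an estimated correlation.

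The neutrophil list against sham, at 1.72 under ISM012-042 (adjusted p = 0.0218), lost its call at 1.06 with a pseudocount of 5, 2.62 with a TPM minimum of 5, 1.23 with array weights, 1.72 with an estimated correlation, 1.44 with the mitochondrial share, 1.46 with both covariates and 1.85 in the libraries of higher Hoxb13. Leaving out 1 library gave 1.03 to 2.06, without a call for sham replicate 4 at 1.67, sham replicate 6 at 1.63 and ISM012-042 replicate 2 at 1.03. The antimicrobial list, at 1.42 without a call, gained one at 1.40 with median-ratio scaling, 1.47 with quantile normalization, 1.48 with Hoxb13 and median-ratio scaling, 1.45 in the libraries of lower Hoxb13 and 1.63 by the exact permutation.

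Leaving out 1 library gave -1.98 to -1.33, -1.21 to -0.96 and -3.07 to -2.42 for the interferon list in vehicle against sham, ISM012-042 against vehicle and ISM012-042 against sham. It gave 2.28 to 3.31 and -1.99 to -0.57 for the neutrophil list in the first and second of these, and 1.95 to 2.32, -0.98 to -0.55 and 1.22 to 1.61 for the antimicrobial list in the 3. For the hypoxia-inducible factor list the ranges were -0.04 to 0.12, -0.13 to 0.05 and -0.05 to 0.06. The shift of higher genes ranged from -0.29 to 0.07 and that of lower genes from -0.13 to 0.06.

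Of 84 named genes 53 passed between vehicle and sham and 18 between ISM012-042 and sham, and none changed direction while called. In 1252 values under the other alternatives calls were lost in 91 and gained in 74 for the former, and lost in 17 and gained in 178 for the latter. In 1008 values with 1 library left out calls were lost in 172 and 50 and gained in 9 and 12. The replicate numbers did not pair libraries across groups, since deviations correlated at 0.0182 for equal numbers and -0.0031 for others, and 5 of 36 best matches had the own number. The depth behind the TPM is unknown, so its limit on low genes cannot be stated.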

Other observations

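The genes of this part and the tests on them were chosen after their values were seen. No list of circadian clock genes was fixed beforehand, so what follows holds for single genes in limma (vehicle against sham, n = 6 per group). Dbp, a transcription factor with a strong daily rhythm, fell by 1.77 ± 0.33 (adjusted p = 0.00685), and the repressor Nr1d1 fell by 1.72 ± 0.26 (0.00230). Nr1d2 fell by 0.91 ± 0.21 (0.0173) and Per3 fell by 1.08 ± 0.30 (0.0448, passing in 11 of 27 alternatives against 27 for Nr1d2), while Nfil3, which is repressed by Nr1d1, rose by 1.56 ± 0.39 (0.0297, passing in 19). Between ISM012-042 and sham Dbp fell by 1.46 ± 0.33 and Nr1d1 fell by 1.39 ± 0.26, passing in 17 and 27 of 27 alternatives, while Nr1d2 at -0.54 ± 0.21, Per3 at -0.34 ± 0.30 and Nfil3 at 1.29 ± 0.39 did not pass (adjusted p of 0.170, 0.476 and 0.105).

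A different time of day at collection could lower Dbp, Nr1d1, Nr1d2 and Per3 and raise the antiphase genes Arntl, Npas2, Clock and Cry1. The score of the latter differed by -0.38 ± 0.23 (SE, fit on the groups compared), or ± 0.22 with all 18 libraries, with Arntl at -0.64 ± 0.29, Npas2 at -0.56 ± 0.20, Clock at -0.45 ± 0.27 and Cry1 at 0.12 ± 0.34. This lies within 2 SE of 0, so the time of collection stays open, and the labels give no hour. The score of Dbp, Nr1d1, Nr1d2 and Per3 differed by -1.37 ± 0.27, and by -1.16 ± 0.27 with the Hoxb13 level as a covariate (-1.27 ± 0.27 with all 18 libraries), which argues against position along the colon as the whole cause. The colitis itself remains an untested biological explanation.

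The acute-phase protease inhibitor Serpina3n rose by 2.93 ± 0.51 in vehicle (adjusted p = 0.00510 in limma) and by 3.64 ± 0.51 in ISM012-042 (0.00181) against sham. Acot1, which encodes an acyl-CoA thioesterase, rose by 1.51 ± 0.41 and 1.74 ± 0.41 (0.0440 and 0.0411), passing in 11 and 12 of 27 alternatives. The transcription factor Creb3l3 rose by 1.51 ± 0.35 in vehicle (0.0174) and stood at 1.33 ± 0.35 in ISM012-042 without passing (0.0595). Fkbp5, a glucocorticoid-induced gene, stood at 1.46 ± 0.42 in vehicle without passing (0.0525) and rose by 1.76 ± 0.42 in ISM012-042 (0.0407, passing in 15 of 27 alternatives). With median-ratio scaling Creb3l3 passed in ISM012-042 and Fkbp5 passed in vehicle and not in ISM012-042 (adjusted p of 0.0669).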
